A study of Mus musculus with 6 samples.

How the data were processed

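The data are 3′ single-cell RNA sequencing libraries of live sorted cells from crypt-enriched small intestine of 3 Fgfr1op knockout (KO) and 3 wild type (WT) samples, at day 6 after tamoxifen per the labels. The authors deposited UMI counts per gene and cell barcode, 1 matrix per sample, with no normalization. Per the submitters' processing notes, Cell Ranger 6.0.1 and Seurat 4.0.1 were used with the mouse genome build mm10, and the role of Seurat is not stated. All values in the matrices were whole numbers of at least 1. Depth ranged from 104611535 to 166867209 UMIs per library, and tests on sums of cells read the spread between libraries, not counting error alone. Every pair of libraries, within a genotype or not, differed far beyond the sampling noise of its counts. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

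Barcodes with at least 500 detected genes and at most 25% mitochondrial UMIs were kept. Doublets were scored per library with scrublet in scanpy 1.11.5. The expected share of cells with the highest scores was marked and removed, because scrublet's automatic threshold marked 0.0441% of cells. Counts were normalized to 10000 UMIs per cell and log transformed on Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). The 2000 most variable genes, 40 principal components and 20 neighbours were used for Leiden clustering at resolution 1 (igraph 0.11.9). Clusters were named from fixed markers of 17 classes. A marker counted as detected where its CPM, with 5 added, was at least 4 times the lower quartile over clusters and where it reached 10% of the highest cluster. A cluster took the class with the largest share of markers detected, at least 3. Where at least 50% of the markers of further classes were detected and the 10 leading genes did not settle it, a cluster of stem cell and transit-amplifying markers was named stem-like, one of other epithelial classes mixed, and any other was left unnamed. Clusters of few UMIs for their samples were left unnamed too. The naming rule was adjusted after clusters of the alternatives were seen. The stem-like class is cluster 14, compared by its number, in which more of the transit-amplifying (91.3%) than of the stem cell markers (52.9%) were detected.

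UMI counts were summed per library and class where the library held at least 20 cells of the class. They were compared with edgeR 4.0.16 (TMM factors, filterByExpr by genotype, robust dispersion, quasi-likelihood F test) on R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p threshold of 0.05. Log2 changes are KO over WT, and CPM values are edgeR counts scaled by the summed UMIs times the TMM factor. Class sizes were compared by exact two-sided permutation tests on shares, with 0.1 as the smallest p, and by an edgeR count model. The KO effect in cluster 14 was compared with that in enterocyte-like cells by an interaction term with each sample as a block. Of 45 fixed lists, those with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera and an estimated correlation, and with fry. A list with at least 3 genes among the markers of a class was not read in that class, a rule set after list calls were seen. The weight given to fry over camera was chosen after other splits of the samples were seen, and fry was not refitted with libraries left out. Phases were called from 35 S and 30 G2/M genes on cells thinned to 10000 UMIs, and shares of cells with an Lgr5 UMI on cells thinned to 2000 UMIs.

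Named genes are the target, the 10 largest rises and falls per class (5 in the smaller classes) among genes called, with at least 20 CPM in 1 genotype and no overlap between genotypes, and up to 4 members with the smallest adjusted p of each list called or with at least 2 passing members. Markers of the class itself and gene models without a name were skipped. The results of 1 fixed list, with the genes named from it, are not reported here.

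The scripts were tested on negative binomial counts simulated from the mean levels, dispersions and totals of the real libraries, with 200 changed genes. Each gene was drawn on its own. The simulation therefore cannot show how list tests or false calls behave where genes are correlated. For the epithelial comparison (14256 genes) the test recovered 73.2% of genes changed by a factor of 2, with 13.2% of its calls false. For cluster 14 (10651 genes) it recovered 81.2%, with 9.60% of its calls false. In Paneth-like cells it recovered 57.9%, in enteroendocrine-like 32.4%, in tuft-like 67.4% and in T cell-like cells 54.0% of such genes. In simulated data for cluster 14, camera and fry called the raised p53 list, and camera with an estimated correlation did not call it. Beside it, camera called 1 and fry 2 other lists.

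The alternatives fixed in advance were relative log expression size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each library left out, predicted doublets kept, at most 10% mitochondrial UMIs, at least 1000 genes, resolution 2, clusters learned on WT cells, free RNA genes left out, all libraries thinned to the smallest total, called genes left out of the clustering, other denominators and scalings of class sizes, and other thinning of phase calls. Chosen after seeing the data were cells with at least 10000 UMIs, WT1 as the lone WT library, clusters 7 and 3 alone, and stem-like and transit-amplifying-like cells together. Relative log expression moved the median log2 change of all genes by at most 0.012. Barcodes in unnamed clusters, 6190 in all, were left out. Clusters 0, 6 and 16 were unnamed for their few UMIs although they detected class markers, and cluster 23 (61 barcodes) because its leading genes went against its markers. Figures were drawn with matplotlib 3.10.9.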

Results

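Live single cells of crypt-enriched mouse small intestine were profiled by 3′ single-cell RNA sequencing with unique molecular identifiers (UMIs). The 6 libraries came from 3 knockout (KO) samples for Fgfr1op and 3 wild type (WT) samples, all taken at day 6 after tamoxifen per the labels. Fgfr1op encodes a centrosomal protein, and the series title ties a centrosomal defect of intestinal stem cells to Crohn's disease. The comparison of KO with WT asks how crypt cells differ after the gene is lost. The libraries held 109227121, 128747888 and 153743290 UMIs in KO1, KO2 and KO3. They held 140711508, 166867209 and 104611535 UMIs in WT1, WT2 and WT3. Of 69394 barcodes, 40810 passed the limits on detected genes and mitochondrial UMIs, and 36975 stayed after 3835 predicted doublets were removed. Of these, 30785 fell into clusters that marker genes named, and 30228 of them were epithelial. The median UMIs per named cell were 9678, 14357 and 21724 in KO1 to KO3 and 10266, 23533 and 15251 in WT1 to WT3. Clusters of barcodes with few UMIs, numbered 0, 6 and 16, held 2.90% ± 2.05 of the KO cells and 26.5% ± 19.4 of the WT cells (SD, n = 3; exact permutation p = 0.2). The value was 4.26% in WT1, 39.97% in WT2 and 35.3% in WT3, and these barcodes entered no comparison. Cluster 0, with 3017 of its 3079 barcodes from WT2, detected 94.7% of the Paneth cell markers. Cluster 6, with 2085 of 2267 from WT3, detected 60.9% of the transit-amplifying markers, and cluster 16 (783 barcodes) 61.5% of the enterocyte markers. The p-values below measure the spread between samples, except those of camera, which compare a list with other genes. The labels do not say separately which animals the samples came from. Cell classes are named by their markers and are called "like" that cell type.

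Fgfr1op (ENSMUSG00000069135, mm10, chromosome 17, 8165501 to 8196804, plus strand, 12 exons in the principal transcript) was lower in each KO library than in each WT library. In epithelial cells it stood at 6.00, 5.98 and 6.28 CPM (UMI counts scaled to a common total) in KO1 to KO3 and at 8.48, 10.3 and 8.28 CPM in WT1 to WT3. The means were 6.09 ± 0.17 CPM in KO and 9.03 ± 1.13 CPM in WT (SD, n = 3), from 502 to 1264 UMIs per library, and edgeR gave a log2 change of −0.57 (SE 0.11, adjusted p = 0.0231). In the stem-like cluster 14 it fell from 18.8 ± 1.84 to 11.7 ± 0.64 CPM (SD, n = 3; log2 −0.71, SE 0.14, adjusted p = 0.0052). In transit-amplifying-like cells it fell from 20.3 to 10.8 CPM (log2 −0.92, SE 0.12, adjusted p = 0.0020), and in enterocyte-like cells from 5.87 to 4.21 CPM (log2 −0.48, SE 0.098, adjusted p = 0.0192). In goblet-like cells the log2 change was −0.37 (adjusted p = 0.193) and in Paneth-like cells 0.13 (adjusted p = 0.933), and the gene was not tested in enteroendocrine-like, tuft-like and T cell-like cells. The annotated 3′ untranslated region of the principal transcript runs from 8194593 to 8196475. The labels do not say which part of the gene was deleted, so 3′ tags that lie outside that part would check nothing about it. In all epithelial cells the call was lost without KO1 (adjusted p = 0.0577), KO2 (0.0961), KO3 (0.0722) or WT1 (0.0673), and with WT1 as the lone WT library (log2 −0.48, adjusted p = 0.0903). In enterocyte-like cells it was lost without KO2 (adjusted p = 0.0805), WT1 (0.0596) or WT3 (0.0577) and with WT1 as the lone WT library (0.180). Within cluster 7 of that class the log2 change was −0.75 (adjusted p = 0.105), and within cluster 3 the gene was not tested. In cluster 14 and transit-amplifying-like cells it was kept with each library left out.

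**Figure D1:**
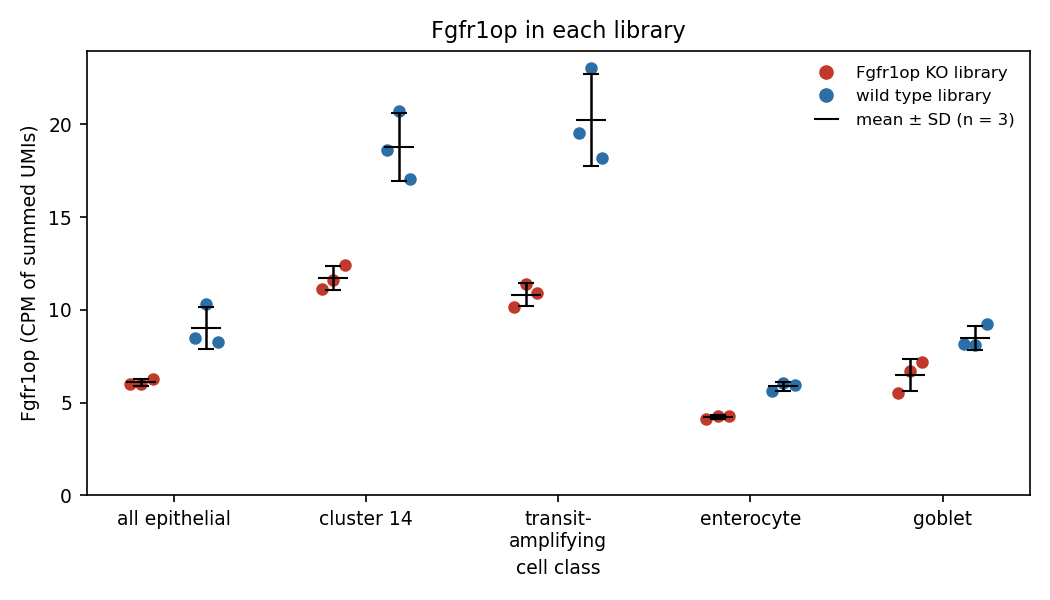
Fgfr1op in CPM in each library (points), with mean and SD (bars), for KO and WT in all epithelial cells, cluster 14, transit-amplifying-like, enterocyte-like and goblet-like cells. In all epithelial cells the KO libraries lie between 5.98 and 6.28 and the WT libraries between 8.28 and 10.3.

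Secretory classes made up smaller shares of the epithelial cells in the KO libraries. Paneth-like cells, which secrete antimicrobial peptides at the crypt base, made up 1.02% ± 0.40 of KO and 5.86% ± 3.66 of WT epithelial cells (SD, n = 3). Enteroendocrine-like cells made up 0.39% ± 0.06 of KO and 0.83% ± 0.30 of WT cells, tuft-like cells 0.52% ± 0.064 and 1.07% ± 0.41, and mucus-secreting goblet-like cells 8.38% ± 0.78 and 12.0% ± 2.41 (SD, n = 3). Each of these 4 classes had no overlap between genotypes, which chance gives a class in 10% of cases, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. The shares of the stem-like cluster 14 (2.97% ± 0.66 in KO, 3.55% ± 1.51 in WT, p = 0.7), transit-amplifying-like cells (8.81% ± 1.93 and 6.56% ± 2.38, p = 0.3) and enterocyte-like cells (76.9% ± 3.64 and 68.9% ± 9.74, p = 0.3) overlapped (SD, n = 3; exact permutation tests). T cell-like cells were 1.61% ± 0.56 of KO and 1.42% ± 0.83 of WT cells (exact permutation p = 0.8). The lowest p adjusted over the 8 classes was 0.2. A count model with edgeR gave log2 changes of −2.51 for Paneth-like (SE 0.57, adjusted p = 0.0145), −1.06 for enteroendocrine-like (SE 0.35, adjusted p = 0.045), −1.03 for tuft-like (SE 0.35, adjusted p = 0.045) and −0.52 for goblet-like cells (SE 0.27, adjusted p = 0.18). With the genes called in the sum of all epithelial cells left out of the clustering, the shares were 1.06% ± 0.40 and 5.04% ± 3.60 for Paneth-like (SD, n = 3; exact permutation p = 0.1). Genes called only within a single class stayed in. They were 8.36% ± 0.78 and 12.0% ± 2.52 for goblet-like cells (SD, n = 3; exact permutation p = 0.2). The shares were then 0.40% in KO and 0.82% in WT for enteroendocrine-like and 0.52% and 1.02% for tuft-like cells, and the count model no longer passed for either (adjusted p = 0.056 each). Over all kept cells, unnamed ones included, the count model gave −0.057 for goblet-like (adjusted p = 0.77), −0.59 for enteroendocrine-like (0.14), −0.56 for tuft-like (0.14) and −1.94 for Paneth-like cells (0.0379). With at most 10% mitochondrial UMIs it gave −0.62 for enteroendocrine-like (adjusted p = 0.40), −1.94 for tuft-like (adjusted p = 0.0163) and −2.61 for Paneth-like cells (adjusted p = 0.0134), and with at least 1000 genes no class passed, the lowest being Paneth-like (−1.87, adjusted p = 0.0502). With predicted doublets kept, enteroendocrine-like (−0.78, adjusted p = 0.081) and tuft-like cells (−0.84, adjusted p = 0.0521) did not pass, and transit-amplifying-like cells did (0.76, adjusted p = 0.0493). Among cells with at least 10000 UMIs, Paneth-like cells were 1.18% of KO and 3.62% of WT cells (exact permutation p = 0.2), and the count model gave −1.60 for Paneth-like and −1.95 for tuft-like cells (adjusted p = 0.0473 each). In the single libraries the Paneth-like share was 0.871%, 0.719% and 1.48% in KO1 to KO3 and 1.89%, 9.10% and 6.60% in WT1 to WT3, and WT2 and WT3 also held the most barcodes with few UMIs. Of the 354 Paneth-like barcodes in cluster 19 (medians of 2737.5 UMIs and 654 genes), 172 came from WT2 and 132 from WT3. Cluster 17, the other Paneth-like cluster, held 81 of 5949 epithelial cells in KO3 and 77 of 5765 in WT1. The lack of overlap was thus not shown for cluster 17 alone. The same holds for goblet-like cluster 9, which held 464 of 5949 epithelial cells in KO3 and 371 of 5765 in WT1. Cluster 15, the other goblet-like cluster (medians of 5568 UMIs and 13.2% mitochondrial UMIs), held 18.5% of KO and 35.9% of WT goblet-like cells. Without WT2 no class passed the count model (Paneth-like log2 −2.04, enteroendocrine-like −0.73 and tuft-like −0.67, each with adjusted p = 0.0577). The enteroendocrine-like and tuft-like calls were both lost without KO1 (adjusted p = 0.187), KO2 (0.194), KO3 (0.0971) and WT3 (0.0669), and without WT1 the goblet-like class passed as well (log2 −0.68, adjusted p = 0.0400).

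**Figure D2:**
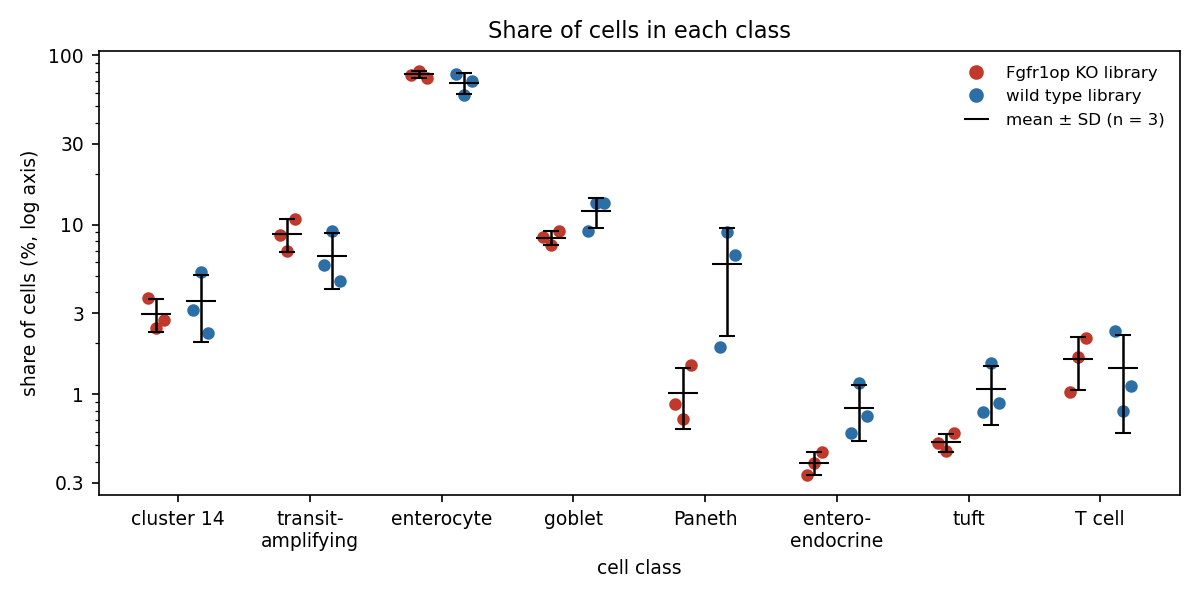
Share of cells in percent (log axis) of 8 cell classes in each KO and WT library (points), of epithelial cells for the epithelial classes and of all kept cells for T cell-like cells, with mean and SD. Paneth-like cells lie between 0.719% and 1.48% in KO and between 1.89% and 9.10% in WT.

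Lgr5, a receptor that marks cycling crypt base stem cells, was seen in a smaller share of KO than of WT cells of cluster 14 after thinning. With each cell thinned to 2000 UMIs, 2.92% ± 0.74 of KO and 6.90% ± 1.24 of WT cells of cluster 14 held an Lgr5 UMI (SD, n = 3; exact permutation p = 0.1). The shares rest on 143, 142 and 159 cells in KO1 to KO3 and 179, 244 and 91 in WT1 to WT3. Without thinning they were 22.8%, 19.6% and 20.7% in KO1 to KO3 and 36.5%, 41.9% and 22.6% in WT1 to WT3. Unthinned, KO1 and WT3 thus overlapped. Lgr5 belongs to the stem cell list, which shares genes with the markers that named cluster 14, so these shares alone decide nothing about stem cells. The thinned share in T cell-like cells, which should lack the gene, was 0% in KO and 0.62% in WT, all of it from WT2 (1.85% of 54 cells). Before thinning, median depths in KO and WT were 4092 and 4529 UMIs in T cell-like cells and 33905 and 27967 UMIs in cluster 14. In transit-amplifying-like cells the thinned shares were 0.96% ± 0.83 and 2.12% ± 0.51 (SD, n = 3; exact permutation p = 0.1). The unthinned shares there overlapped, at 10.6%, 3.45% and 5.75% in KO1 to KO3 and 9.58%, 19.1% and 10.1% in WT1 to WT3. Phase calls on cells thinned to 10000 UMIs put 60.5% ± 6.22 of KO and 62.8% ± 6.02 of WT cells of the stem-like and transit-amplifying-like classes together in S or G2/M (SD, n = 3; exact permutation p = 0.7). Within cluster 14, S calls were 54.6% ± 4.68 and 58.5% ± 4.11 (exact permutation p = 0.3) and G2/M calls 19.5% ± 3.27 and 8.34% ± 2.04 (SD, n = 3; exact permutation p = 0.1). Whether free RNA enters these calls was not tested, and they carry no statement on cycling.

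Across all epithelial cells, Areg, Tnfrsf12a and Cxcl16 were among the largest rises. Areg (ENSMUSG00000029378), which encodes a ligand of the epidermal growth factor receptor, rose from 13.5 ± 3.06 CPM in WT to 65.6 ± 7.17 CPM in KO (SD, n = 3; log2 2.28, SE 0.17, adjusted p = 0.0019). Tnfrsf12a (ENSMUSG00000023905), the receptor of the cytokine TWEAK, rose from 5.44 ± 1.29 to 30.7 ± 4.98 CPM, and the chemokine gene Cxcl16 from 8.003 ± 1.41 to 42.6 ± 11.5 CPM (SD, n = 3). Ckb (ENSMUSG00000001270), the brain type creatine kinase, rose from 252 ± 38.2 to 951 ± 62.0 CPM (SD, n = 3; log2 1.92, SE 0.12, adjusted p = 0.0014). Mboat1, an acyltransferase of phospholipids, rose by 2.51 (log2), the dual specificity phosphatase gene Dusp8 by 2.39, the aldo-keto reductase gene Akr1b8 by 1.87 and Nos2, the inducible nitric oxide synthase, by 1.75. Gng11, a G protein subunit, fell from 23.1 ± 1.54 to 7.96 ± 0.29 CPM (SD, n = 3; log2 −1.54), and Mettl7b fell by 1.53 on the log2 scale. Cd36, a fatty acid transporter, fell from 9.36 ± 2.92 to 1.23 ± 0.47 CPM (SD, n = 3; log2 −2.93). Ciita, the master regulator of MHC class II genes, fell from 9.90 ± 2.21 to 2.91 ± 0.31 CPM (SD, n = 3; log2 −1.76). Ripk3, a kinase of necroptosis, rose from 21.1 ± 2.08 to 50.8 ± 2.69 CPM (SD, n = 3; log2 1.26). Each gene named in this paragraph had all 3 KO libraries beyond all 3 WT libraries and kept its call with each library left out. Further falls that kept it in 4 or fewer of these 6 fits were the receptor gene Cubn (log2 −2.53), the phospholipase gene Plb1 (−1.71), Gsdmc4 (−1.67), H2-Aa (−1.66) and Lct (−1.58).

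In this test of all epithelial cells, 2127 of 14403 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 1079 higher and 1048 lower in KO, and 526 of them changed by more than 1 on the log2 scale. All 2127 had no overlap between genotypes, as did 38.6% of the genes tested, where chance gives 10%. The count was 1055, 223 and 364 without KO1, KO2 and KO3 and 462, 3704 and 834 without WT1, WT2 and WT3, and 569 with WT1 as the lone WT library. In all, 200 genes were called in every one of these 6 fits.

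More genes rose than fell among p53 targets and among genes of regenerating epithelium. Of 26 measured p53 targets, 14 rose, 0 fell and 12 did not pass (16 rose when adjusted over the list alone), with a median log2 change of 0.47. Ccng1 (cyclin G1) rose from 24.5 ± 0.96 to 52.4 ± 2.88 CPM, the apoptosis effector Bax from 80.7 ± 3.07 to 143 ± 2.11 CPM, and Phlda3 from 0.196 ± 0.080 to 6.00 ± 1.57 CPM (SD, n = 3). Of 13 genes of regenerative and fetal-like epithelium, 3 rose, 1 fell and 9 did not pass (7 rose and 1 fell when adjusted over the list alone), with a median of 0.64. The rotation test fry of limma, which tests whether a set's genes move one way on balance and does not compare the set with other genes, gave adjusted p = 0.0045 for p53 targets and 0.0070 for the regenerative list. With camera and an estimated correlation the adjusted p was 0.26 for each of these lists. Genes of dissociation and immediate early response stood at 3992 ± 464 CPM in KO and 3152 ± 113 CPM in WT (SD, n = 3), without overlap.

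Markers of goblet cells were lower in the epithelium as a whole, and those of other secretory cells were lower without passing as lists. Of 11 goblet cell genes, 7 fell, 0 rose and 4 did not pass (9 fell when adjusted over the list alone; median log2 −0.47; fry adjusted p = 0.037; adjusted p = 0.85 with an estimated correlation). Fcgbp, a component of mucus, fell from 2977 ± 255 to 1427 ± 69.3 CPM (SD, n = 3; log2 −1.06). Of 12 tuft cell genes, 11 fell and 1 did not pass (11 when adjusted over the list alone; median log2 −1.30; fry adjusted p = 0.064), among them Ltc4s (log2 −1.10) and Alox5ap (−1.69), both of leukotriene synthesis. The Paneth cell list (15 of 15 genes lower, median log2 −1.13) and the enteroendocrine list (14 of 15 lower, −0.65) did not pass fry (adjusted p = 0.39 each), and 15 genes of each did not pass edgeR. Of 22 intestinal stem cell genes, 1 fell and 21 did not pass (0 when adjusted over the list alone), 20 had a lower and 2 a higher value in KO, and the median was −0.40 (fry adjusted p = 0.40). These lists were read over all epithelial cells, in which the shares of the classes differed. Of 17 genes of the NF-kB and TNF response, 3 rose, 0 fell and 14 did not pass (3 rose when adjusted over the list alone; median log2 0.15; fry adjusted p = 0.038; adjusted p = 0.66 with an estimated correlation), with Cxcl16 as the largest rise.

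In the stem-like cluster 14, which led with Olfm4, Ifitm3, Hells and Mcm3, Tnfrsf12a and Ckb rose and Ceacam10 and S100g fell. Tnfrsf12a rose from 9.07 ± 2.04 to 44.2 ± 8.97 CPM (SD, n = 3; log2 2.30, SE 0.19, adjusted p = 1.7e-05). Ckb rose by 2.26 (log2), Mboat1 by 2.32, Akr1b8 by 2.51 and Ddah1, which breaks down dimethylarginines, by 1.78. Ceacam10 (ENSMUSG00000054169), a cell adhesion gene, fell from 71.2 ± 6.06 to 16.6 ± 2.47 CPM (SD, n = 3; log2 −2.11, SE 0.12, adjusted p = 4.0e-07). The calcium-binding gene S100g fell from 27.4 ± 4.26 to 6.21 ± 1.41 CPM (SD, n = 3; log2 −2.12). The ligand genes Gas6 (log2 −1.66) and Tnfsf10 (−1.64) and the genes Tcea3 (−1.88), Gng11 (−1.79), Klhl24 (−1.33) and Camk2n1 (−1.31) also fell. Each of these genes kept its call with each library left out, while Gsta1 (log2 3.00), S100a6 (2.46) and Selenop (−1.46) kept it in 3 or fewer of the 6 fits. The class is a cluster compared by its number, and it held 52.9% of the stem cell and 91.3% of the transit-amplifying markers, with 1 and 2 of them among its 10 leading genes.

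Several gene groups moved in cluster 14. Of 25 p53 targets, 11 rose, 0 fell and 14 did not pass (13 rose when adjusted over the list alone; median log2 0.47). Bax rose from 117 ± 7.70 to 184 ± 9.88 CPM and Gdf15, a stress-induced cytokine, from 3.10 ± 0.35 to 14.7 ± 4.03 CPM (SD, n = 3). Of 6 regenerative and fetal-like genes, 3 rose, with Areg from 2.83 ± 0.65 to 18.4 ± 2.00 CPM and Emp1 from 7.61 ± 1.89 to 14.8 ± 2.29 CPM (SD, n = 3). The log2 change of Emp1 in stem-like cells was −0.028 where predicted doublets were kept. The other 3 did not pass (3 rose and 1 fell when adjusted over the list alone). Of 15 genes of the integrated stress response, 6 rose, 0 fell and 9 did not pass (7 rose and 2 fell when adjusted over the list alone; median log2 0.51). Psat1, an enzyme of serine synthesis, rose by 1.13 (log2) and the transcription factor gene Atf4 by 0.40. Of 17 genes of the MHC and interferon gamma response, 6 fell, 0 rose and 11 did not pass (11 fell when adjusted over the list alone; median log2 −0.80). The immunoproteasome genes Psmb8 and Psmb9 fell from 169 ± 16.4 to 83.0 ± 5.85 CPM and from 120 ± 14.1 to 69.3 ± 1.35 CPM (SD, n = 3). All 13 genes of the mitochondrial genome fell when adjusted over the list alone and 8 over all genes (5 did not pass; median log2 −0.68). The median mitochondrial share of UMIs per named cell was 6.13% ± 0.50 in KO and 7.14% ± 0.92 in WT (SD, n = 3). With fry the adjusted p was 0.024 for each of these 5 lists, and with an estimated correlation it was 0.41. Genes of dissociation and immediate early response stood at 4985 ± 488 CPM in KO and 4054 ± 231 CPM in WT (SD, n = 3). Hes1 (log2 −0.77), Notch1 (−0.92) and Sox4 (−0.82), from the list of Notch signalling and secretory specification, fell. Their list of 10 genes, with 1 up and 4 down, did not pass (1 up and 4 down when adjusted over the list alone; fry adjusted p = 0.40).

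The test of cluster 14 called 1685 of 10754 genes, 846 higher and 839 lower, 314 of them by more than 1 on the log2 scale. Of these, 1662 had no overlap (98.6%), as did 36.6% of the genes tested, where chance gives 10%. The count was 702, 797 and 893 without KO1, KO2 and KO3, 444 without WT1 and 2637 without WT2, and 403 genes were called in all 6 such fits. Of 31 genes of centrosome and centriole, the structure that Fgfr1op belongs to, 1 rose and 1 fell (0 rose and 1 fell when adjusted over the list alone), with a median of −0.05 (fry adjusted p = 0.32). These were Plk4, the kinase that starts centriole duplication (log2 0.41, called in 2 of the 6 fits), and Sdccag8 (log2 −0.68, called in 5).

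Transit-amplifying-like cells showed rises and falls in many of the genes named for cluster 14. Tnfrsf12a rose from 6.76 ± 1.99 to 45.2 ± 5.73 CPM (SD, n = 3). Ckb rose from 103 ± 23.0 to 596 ± 32.2 CPM (log2 2.53, SE 0.15, adjusted p = 4.6e-05) and Dusp8 from 4.07 ± 0.26 to 27.0 ± 3.48 CPM (SD, n = 3). Ceacam10 fell from 35.8 ± 2.08 to 8.50 ± 0.43 CPM (SD, n = 3; log2 −2.07, SE 0.10, adjusted p = 9.85e-06), Gas6 by 1.94 and S100g by 2.02 on the log2 scale. Of 9 genes of Notch signalling and secretory specification, 6 fell, 0 rose and 3 did not pass (7 fell when adjusted over the list alone; median log2 −0.82). Among them Atoh1, which commits progenitors to secretory fates, fell from 4.33 ± 0.91 to 1.52 ± 0.23 CPM (SD, n = 3). Spdef, a regulator of goblet cell maturation, fell from 5.33 ± 1.35 to 1.69 ± 0.19 CPM, and the Notch ligand Dll1 from 10.7 ± 2.53 to 5.11 ± 0.58 CPM (SD, n = 3). The class leaves out the mixed cluster 20 (334 cells), of transit-amplifying and goblet markers, which had Spdef and Atoh1 among its 10 leading genes. Cluster 20 made up 1.01% ± 0.31 of KO and 1.19% ± 0.66 of WT epithelial cells (SD, n = 3; exact permutation p = 0.8). Levels of these genes within cluster 20 were not tested. Of 11 goblet cell genes, 9 fell, 0 rose and 2 did not pass (10 fell when adjusted over the list alone; median log2 −1.61), with Fcgbp at log2 −2.18 and Agr2 at −1.26. Goblet cell genes were also lower in KO T cell-like cells, at 1548 ± 271 CPM against 4562 ± 1630 CPM in WT (SD, n = 3; log2 −1.51), and at −0.04 within goblet-like cells. Of 14 Paneth cell genes, 4 fell and 10 did not pass (14 fell when adjusted over the list alone; median log2 −2.14; fry adjusted p = 0.099). In T cell-like cells the Paneth cell genes stood at 2377 ± 827 CPM in KO and 11466 ± 7441 CPM in WT (SD, n = 3; log2 −2.10).

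In the same class 13 of 25 p53 targets rose, 0 fell and 12 did not pass (15 rose when adjusted over the list alone; median log2 0.65), with Bax from 105 ± 10.4 to 189 ± 10.2 CPM (SD, n = 3). Of 10 regenerative and fetal-like genes, 5 rose and 5 did not pass (5 rose when adjusted over the list alone; median log2 1.02). Of 19 apoptosis genes, 5 rose and 14 did not pass (5 rose when adjusted over the list alone; median log2 0.19). Bbc3, which encodes PUMA, rose from 2.72 ± 0.51 to 5.41 ± 0.70 CPM (SD, n = 3). Of 12 circadian clock genes, 2 fell and 10 did not pass (2 fell when adjusted over the list alone; median log2 −0.71), Per3 (log2 −1.40) and Per2 (−0.95). Fry gave adjusted p = 0.0059 for p53 targets, 0.0056 for the regenerative, Notch and apoptosis lists, 0.012 for goblet cell genes and 0.033 for the clock. With an estimated correlation the adjusted p was 0.14 for the p53, regenerative and Notch lists, 0.41 for goblet cell genes and 0.47 for apoptosis and the clock. Lgr5 fell from 10.0 ± 4.00 to 3.94 ± 1.45 CPM (SD, n = 3; log2 −1.38, adjusted p = 0.026, called in 4 of the 6 fits). Of 22 stem cell genes, 3 fell (5 when adjusted over the list alone; median log2 −0.41; fry adjusted p = 0.26). Genes of dissociation and immediate early response stood at 4771 ± 623 CPM in KO and 3863 ± 214 CPM in WT (SD, n = 3). In all 1796 of 11609 genes were called, 946 higher and 850 lower. The count was 795, 511 and 527 without KO1, KO2 and KO3 and 534 without WT1.

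**Figure D3:**
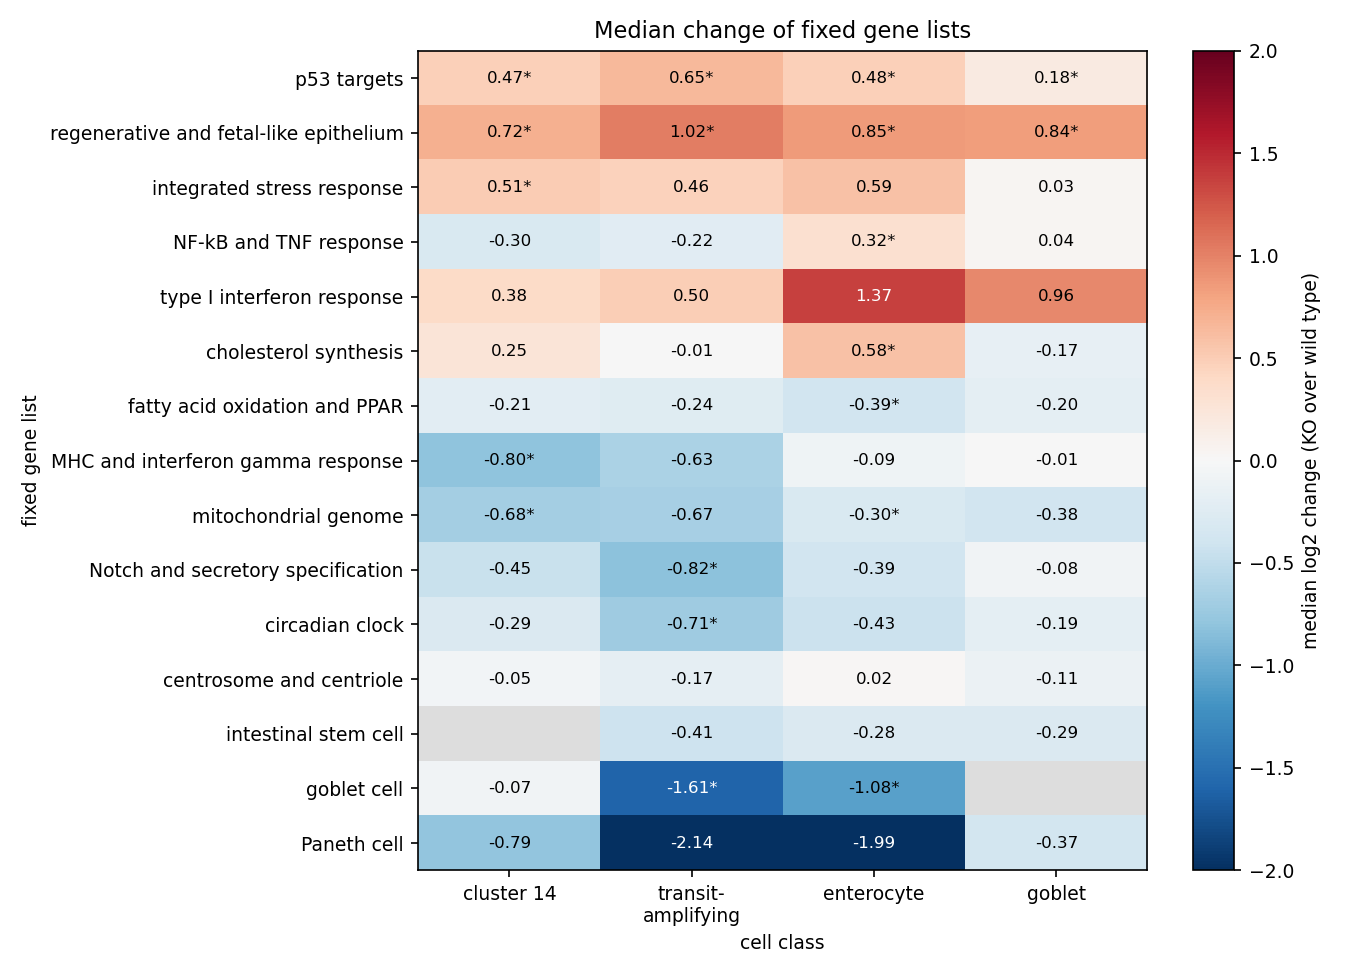
Median log2 change (KO over WT) of 15 fixed gene lists in cluster 14, transit-amplifying-like, enterocyte-like and goblet-like cells, as colour and printed value, with a star where the adjusted p of fry is under 0.05 and grey where a list defines the class. The medians of p53 targets are 0.47, 0.65, 0.48 and 0.18 in the 4 classes.

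In enterocyte-like cells Areg, Tnfrsf12a and Ckb rose and lipid genes changed. Areg rose from 18.8 ± 4.93 to 92.4 ± 16.7 CPM, Tnfrsf12a from 4.29 ± 1.13 to 27.8 ± 5.87 CPM and Ckb from 384 ± 119 to 1257 ± 23.3 CPM (SD, n = 3). The B cell linker gene Blnk rose by 2.02 (log2), the actin-binding gene Cotl1 by 1.71 and the calcium-binding gene S100a11 by 1.69, and Dusp8 rose by 2.60 (SE 0.12, adjusted p = 2.5e-04). Of 18 genes of cholesterol synthesis, 11 rose, 0 fell and 7 did not pass (13 rose and 2 fell when adjusted over the list alone; median log2 0.58). Msmo1, a sterol oxidase, rose from 63.6 ± 5.53 to 109 ± 9.24 CPM and Sqle, squalene epoxidase, from 47.6 ± 7.58 to 94.3 ± 11.2 CPM (SD, n = 3). Of 16 genes of fatty acid oxidation and PPAR, 6 fell, 1 rose and 9 did not pass (10 fell and 1 rose when adjusted over the list alone; median log2 −0.39). Cd36 fell from 14.4 ± 2.54 to 1.88 ± 0.93 CPM (SD, n = 3), and Ppargc1a, a coactivator of mitochondrial genes, was at log2 −0.98, called in 3 of the 6 fits. Of 26 p53 targets, 14 rose, 0 fell and 12 did not pass (17 rose and 2 fell when adjusted over the list alone; median log2 0.48). Ccng1 rose from 24.1 ± 1.39 to 57.2 ± 3.20 CPM and Phlda3 from 0.0226 ± 0.0228 to 5.27 ± 1.06 CPM (SD, n = 3). Of 12 regenerative and fetal-like genes, 5 rose and 7 did not pass (7 rose when adjusted over the list alone; median log2 0.85). Of 17 genes of the NF-kB and TNF response, 5 rose and 12 did not pass (5 rose when adjusted over the list alone; median log2 0.32). Of 13 genes of the mitochondrial genome, 2 fell and 11 did not pass (10 fell when adjusted over the list alone; median log2 −0.30). Fry gave adjusted p = 0.0040 for p53 targets, 0.010 for the regenerative list, 0.021 for the cholesterol, fatty acid and NF-kB lists and 0.025 for the mitochondrial genome. With an estimated correlation the adjusted p was 0.40 for the p53 and regenerative lists and 0.53 for the other 4.

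Paneth and goblet cell genes were lower in enterocyte-like cells too. Of 15 Paneth cell genes, 8 fell, 0 rose and 7 did not pass (15 fell when adjusted over the list alone; median log2 −1.99; fry adjusted p = 0.094). Among the 10 largest falls, 7 were the alpha-defensin genes Defa5, Defa21, Defa22, Defa24 and Defa29, Ang4 and Itln1. The defensin genes have near-identical copies, so their single values are uncertain. Of 11 goblet cell genes, 9 fell, 0 rose and 2 did not pass (10 fell when adjusted over the list alone; median log2 −1.08; fry adjusted p = 0.021; adjusted p = 0.53 with an estimated correlation). The Paneth cell genes were lower by a log2 ratio of −2.10 in T cell-like cells and the goblet cell genes by −1.51. The other 3 of the 10 largest falls were Cubn (log2 −2.50), Dio1, a deiodinase of thyroid hormone (−2.38), and the water channel gene Aqp1 (−1.91), and each of the 10 kept its call in 3 or fewer of the 6 fits. Ciita fell from 13.9 ± 2.88 to 3.81 ± 0.24 CPM and H2-DMa from 63.0 ± 13.6 to 28.1 ± 1.63 CPM (SD, n = 3). Of 25 genes of their list, 4 fell (9 when adjusted over the list alone; median log2 −0.09; fry adjusted p = 0.40). Of 21 type I interferon genes, 1 rose (0 when adjusted over the list alone; fry adjusted p = 0.37). The list stood at 1531, 569 and 423 CPM in KO1 to KO3 and at 453, 503 and 251 CPM in WT1 to WT3. Genes of dissociation and immediate early response stood at 3686 ± 427 CPM in KO and 2890 ± 101 CPM in WT (SD, n = 3).

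The test of enterocyte-like cells called 1964 of 13020 genes, 1047 higher and 917 lower. The count was 520 and 1048 without KO2 and KO3, 506 and 817 without WT1 and WT3, and 235 with WT1 as the lone WT library. Different clusters made up the class in each genotype, with 23.8% of KO cells of the class in cluster 4, 22.7% in cluster 5 and 16.7% in cluster 8, and 28.4% of WT cells in cluster 1 and 29.3% in cluster 2. Within cluster 7, which held 6.13% of KO and 15.1% of WT cells of the class, 601 genes were called, and 64 within cluster 3 (11.7% and 15.7%).

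In goblet-like cells Acta1, Tnfrsf12a, Areg and 5 of 22 p53 targets rose. Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), the skeletal muscle actin, rose from 1.16 ± 0.059 to 29.1 ± 5.13 CPM (SD, n = 3; log2 4.64, SE 0.19, adjusted p = 3.8e-09), and it also passed in cluster 14, transit-amplifying-like and enterocyte-like cells. Tnfrsf12a rose from 7.34 ± 1.24 to 24.2 ± 2.64 CPM and Areg from 11.2 ± 1.31 to 24.1 ± 2.37 CPM (SD, n = 3). The sodium channel gene Scnn1a fell from 49.5 ± 4.37 to 24.0 ± 1.06 CPM and Gng11 from 49.0 ± 4.30 to 23.1 ± 1.33 CPM (SD, n = 3), and Malrd1 fell by 1.27 on the log2 scale. Sct, which encodes the hormone secretin, rose from 366 ± 29.5 to 696 ± 101 CPM (SD, n = 3; log2 0.93). Of 22 p53 targets, 5 rose, 0 fell and 17 did not pass (7 rose when adjusted over the list alone; median log2 0.18), among them the cell cycle inhibitor Cdkn1a from 176 ± 16.3 to 255 ± 16.7 CPM (SD, n = 3). Of 7 regenerative and fetal-like genes, 5 rose and 2 did not pass (5 rose when adjusted over the list alone; median log2 0.84). The annexin gene Anxa3 rose from 55.7 ± 4.06 to 99.8 ± 2.56 CPM (SD, n = 3). Fry gave adjusted p = 0.0049 for p53 targets and 0.0058 for the regenerative list, and with an estimated correlation the adjusted p was 0.16 for each. In all 516 of 10803 genes were called, 268 higher and 248 lower. The count was 217, 78 and 134 without KO1, KO2 and KO3, 88 without WT1 and 1239 without WT2.

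**Figure D4:**
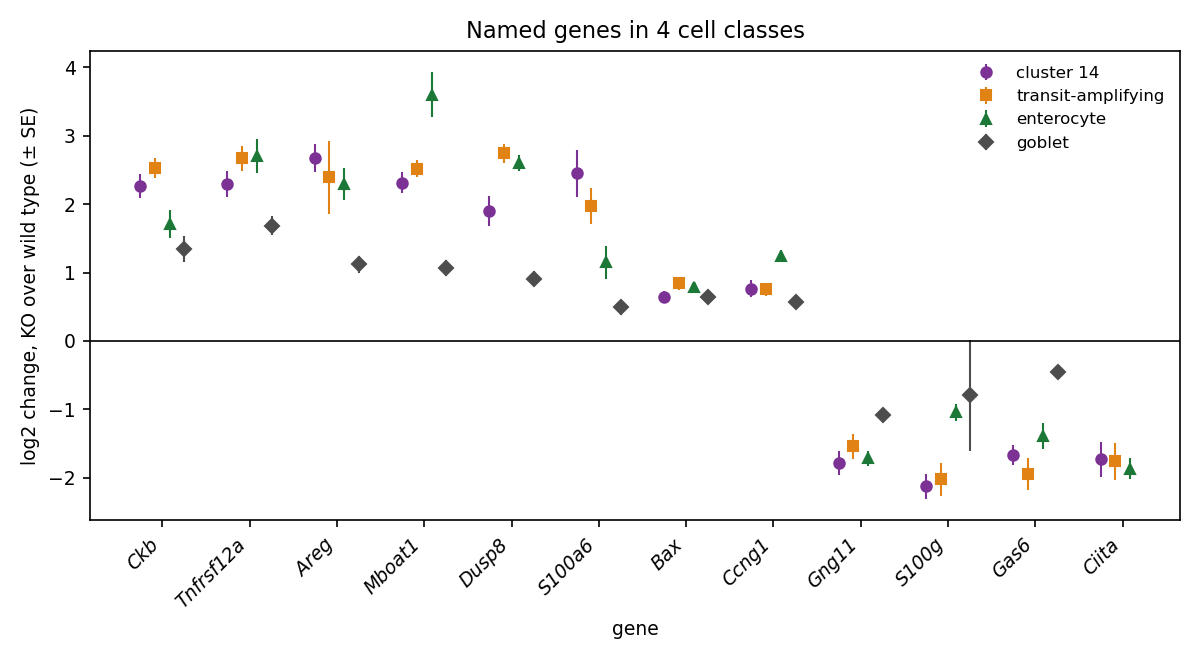
Log2 change (KO over WT) with its SE for 12 named genes in cluster 14, transit-amplifying-like, enterocyte-like and goblet-like cells (points), with a line at 0. Ciita was not tested in goblet-like cells. Tnfrsf12a lies at 2.30, 2.67, 2.70 and 1.69 in the 4 classes.

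The smaller classes held fewer calls. Paneth-like cells fell into cluster 17 (89.0% of KO and 58.3% of WT cells of the class) and cluster 19 (11.0% and 41.7%), with median mitochondrial shares of 4.23% and 0.547%. In Paneth-like cells 18 of 7228 genes passed, 9 in each direction, with Ckb from 21.1 ± 3.80 to 102 ± 36.6 CPM (SD, n = 3; log2 2.25, adjusted p = 3.9e-05). Of 13 genes of the mitochondrial genome in Paneth-like cells, 1 fell and 12 did not pass (12 fell when adjusted over the list alone; median log2 −0.72; fry adjusted p = 0.024; adjusted p = 0.53 with an estimated correlation). In tuft-like cells, chemosensory cells of the epithelium, 30 of 4230 genes passed, 20 higher and 10 lower. Of 11 type I interferon genes in tuft-like cells, 6 rose and 5 did not pass (10 rose when adjusted over the list alone; median log2 1.47). Isg15 rose from 38.3 ± 15.5 to 216 ± 97.5 CPM and Oasl2 from 46.5 ± 5.71 to 144 ± 49.6 CPM (SD, n = 3). The list stood at 1487, 1008 and 979 CPM in KO1 to KO3 and at 473, 356 and 530 CPM in WT1 to WT3 (fry adjusted p = 0.086; adjusted p = 0.49 with an estimated correlation). Pycard, the inflammasome adaptor ASC, fell from 346 ± 25.4 to 133 ± 35.9 CPM in tuft-like cells (SD, n = 3; log2 −1.36), but had a log2 change of 0.058 where predicted doublets were kept. In enteroendocrine-like cells, tested on 2 KO and 3 WT libraries because KO1 held fewer than 20 such cells, 14 of 5094 genes passed, with Ckb as the rise (log2 1.62) and 13 falls. With at most 10% mitochondrial UMIs 5 genes passed, each a rise, and mt-Nd1 in enteroendocrine-like cells was at −0.13. With free RNA genes left out, the mitochondrial ones included, Ckb alone passed. Of 13 genes of the mitochondrial genome in that class, 9 fell and 4 did not pass (12 fell when adjusted over the list alone; median log2 −0.77; fry adjusted p = 0.018; adjusted p = 0.28 with an estimated correlation), with mt-Nd1 at log2 −1.01. In T cell-like cells, 6 of 5589 genes passed and each fell, among them the epithelial genes Fcgbp (log2 −1.92), Muc2 (−1.76), Tff3 (−1.66) and Pigr (−1.31). The count in Paneth-like cells was 9 without KO1, 3 without KO2, 9 without WT1 or WT2 and 75 without WT3. In tuft-like cells it was 7 without KO1, 13 without KO2, 49 without WT1, 7 without WT2 and 122 without WT3. In enteroendocrine-like cells it was 25 without WT1. Leaving out KO2 or KO3 left 1 KO library in that class, so those counts are not read. In T cell-like cells it was 3 without KO2, 59 without WT1, 10 without WT2 and 17 without WT3.

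**Figure D5:**
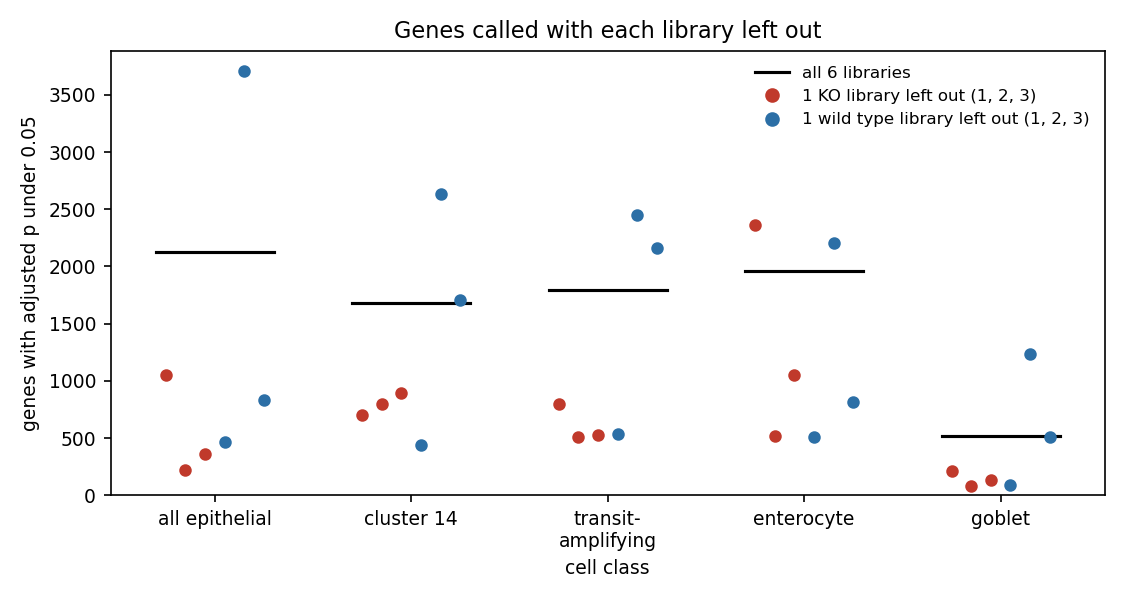
Number of genes called (adjusted p under 0.05) in all epithelial cells, cluster 14, transit-amplifying-like, enterocyte-like and goblet-like cells with each library left out in turn (points), and with all 6 libraries (line). The counts in cluster 14 run from 444 without WT1 to 2637 without WT2, against 1685 with all 6.

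The KO effect was compared between cluster 14 and enterocyte-like cells, which asks whether this cluster of stem cell and transit-amplifying markers responds unlike absorptive cells. S100a6 changed by 1.33 (log2) more in cluster 14, Akr1b8 by 1.02 and Ckb by 0.66, while the changes of Blnk (difference −1.24), Mboat1 (−1.30), Cotl1 (−0.76) and S100a11 (−0.72) were lower there. S100g (difference −1.01) fell further in cluster 14, and Aqp1 (1.17) fell further in enterocyte-like cells. An interaction model with each sample as a block called 318 of 13105 genes, 218 with a higher and 100 with a lower change in cluster 14. The camera test of the interaction put genes of ribosomal proteins (adjusted p = 7.3e-06), the mitochondrial genome (adjusted p = 3.8e-04), the type I interferon response (adjusted p = 0.0088), the MHC and interferon gamma response (adjusted p = 0.011), cholesterol synthesis (adjusted p = 0.010) and the NF-kB and TNF response (adjusted p = 0.010) lower in cluster 14. It put genes of goblet cells (adjusted p = 0.0084) and of fatty acid oxidation and PPAR (adjusted p = 0.010) higher, and the G2/M list, which shares genes with the markers of cluster 14, was not read. Summed goblet cell markers had log2 ratios of −0.20 in cluster 14, −1.07 in enterocyte-like and −1.51 in T cell-like cells. The ratio was −1.50 in transit-amplifying-like cells, so it was not alike in cluster 14 and the class nearest to it in markers. In cluster 14 these markers stood at 1154, 2131 and 874 CPM in KO1 to KO3. Free RNA was not tested as the source of the goblet difference and cannot be told apart from a different response. Different clusters made up the enterocyte-like class in each genotype, and that too cannot be told apart from a different response. For p53 targets (adjusted p = 0.73) and the regenerative list (adjusted p = 0.82) a difference was not detectable. The interferon difference goes with the high KO1 level in enterocyte-like cells, where the list's median was 1.37 with all libraries and 0.43 without KO1. These list tests used camera with a preset correlation, whose calls within the classes were each lost with an estimated correlation. The count was 93 and 151 without KO2 and KO3, 107 without WT1 and 483 without WT3.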

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

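The tests of the 3 patterns weighed here were chosen only after the results were seen, as were the splits of the samples for the gene counts, while the splits for the gene lists were written down before.

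The KO effect differed between cluster 14 and enterocyte-like cells in 318 genes by the test of the difference itself. Among named genes, the change was higher in cluster 14 than in enterocyte-like cells by a log2 difference of 1.33 for S100a6, 1.17 for Aqp1, 1.02 for Akr1b8 and 0.66 for Ckb. It was lower in cluster 14 by −1.30 for Mboat1, −1.24 for Blnk, −1.01 for S100g, −0.76 for Cotl1 and −0.72 for S100a11. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the highest other gave 9, but 10 splits are too few for a share under 0.05.

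Paneth cell genes were lower in KO libraries in enterocyte-like and transit-amplifying-like cells. Free RNA from Paneth cells may be the source, because T cell-like cells, which should not make these genes, showed a log2 ratio of −2.10 against −1.83 in enterocyte-like cells. A lower level of these genes within Paneth cells stays open. Their share of UMIs in Paneth-like cells had a log2 ratio of 0.12, but the genes named the class and made up so much of its UMIs (655750 CPM in WT) that a halved level would give −0.43. Whether fewer Paneth cells in the tissue or a different loss of cells during preparation lowered that free RNA stays open and was not tested.

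Intestinal stem cell genes had lower values in KO epithelium in 20 of 22 members, but 1 member passed and the list did not pass fry (adjusted p = 0.40; 0.86 with an estimated correlation), so a change of the group was not shown. The mean of the median UMIs per cell in cluster 14 was 33905 in KO and 27967 in WT. Single libraries overlapped, with 28828.5 in KO3 and 33870.5 in WT2. In enterocyte-like cells the means were 11469.5 in KO and 13278.8 in WT. Fewer UMIs per KO cell were thus not seen in cluster 14, but the pattern is over all epithelial cells, so this does not settle the question. A smaller share of stem-like cells and a shift between cell cycle phases could each give the pattern and cannot be told apart from a lower level of these genes. The list's median within cluster 14 was −0.59, and within single phases it was −0.29 (S, 232 KO and 268 WT cells) and −1.30 (G1, 109 and 149 cells), but the list shares genes with the markers that named the cluster, so these values decide nothing.

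Type I interferon genes had positive median log2 changes in enterocyte-like and tuft-like cells, where fry did not pass (adjusted p = 0.37 and 0.086). In enterocyte-like cells high levels in KO1 are a candidate explanation for the size of the median, which over 21 genes was 1.37 with all libraries and 0.43 without KO1. Cluster 8 of that class, led by Ubd, Ifit1 and Rsad2, held 937, 717 and 363 cells in KO1 to KO3. WT1 to WT3 gave 90, 63 and 7 of its cells, so high levels in KO1 alone do not account for that cluster. In goblet-like cells the list stood at 854, 466 and 422 CPM in KO1 to KO3. The WT1 to WT3 values there were lower, at 299, 349 and 237 CPM. In tuft-like cells the tables argue against high levels in KO1 alone, since the median was 1.47 with all libraries and 1.295 over 12 genes without KO1. Why KO1 differed in enterocyte-like cells, and whether the tuft-like difference is biological, stays open, because each library held few tuft-like cells and other technical explanations were not tested.

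For the counts of genes called, 1 of the 10 splits of the 6 libraries, the real one, gave as many in each class tested. The real and highest other counts were 2127 and 0 in epithelial cells, 1685 and 0 in cluster 14, 1796 and 0 in transit-amplifying-like, 1964 and 0 in enterocyte-like, 516 and 2 in goblet-like, 18 and 5 in Paneth-like, 30 and 1 in tuft-like and 6 and 2 in T cell-like cells. They were 3 and 1 for the class sizes by the count model and 95 and 90 for lists called by camera, so that camera called nearly as many lists in a split that mixes genotypes (KO1, WT2 and WT3 against the rest). Fry called 31 lists in the real split and at most 6 in another. These splits of the lists left out enteroendocrine-like cells, in which camera called 9 and fry 3 lists. In each case 10 splits are too few for a share under 0.05.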

How the results depend on the processing

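Cells with at least 10000 UMIs, WT1 as the lone WT library, clusters 7 and 3 alone and stem-like with transit-amplifying-like cells were chosen only after the data were seen. For each change below the cause was not tested.

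Of 7939 values of named genes under the alternatives, 6413 kept their direction and call, 1508 kept the direction without the call and 18 reversed. Of 1028 values of lists called by camera, 762 kept both, 266 lost the call and 0 reversed. Counts of genes called with 1 library left out ran from 223 to 3704 in epithelial cells (2127 with all), 444 to 2637 in cluster 14 (1685), 511 to 2453 in transit-amplifying-like (1796), 506 to 2364 in enterocyte-like (1964), 78 to 1239 in goblet-like (516), 3 to 75 in Paneth-like (18), 12 to 56 in enteroendocrine-like (14), 7 to 122 in tuft-like (30) and 3 to 59 in T cell-like cells (6). In the same fits the target gene ran from −0.62 to −0.47, lists called by camera from 91 to 108 (104), class sizes called from 0 to 4 (3), classes without overlap from 4 to 5 (4), the interaction from 93 to 483 (318) and the difference in cycling share from −5.58 to 0.67 (−2.32). Paneth-like counts fell to 3 without KO2. Enteroendocrine-like cells had no separate fit without KO1, which held too few cells and was already out of every fit of that class. Leaving out KO2 or KO3 thus left 1 KO library in that class. The upper end of its range came from the fit without KO3 and is not read. With KO2 and KO3 both kept, its counts were 25, 12 and 20 without WT1, WT2 and WT3. No value could be had for tuft-like cells at 10% mitochondrial UMIs, or for tuft-like, enteroendocrine-like and T cell-like cells at 10000 UMIs, because too few cells were left. In the small classes the simulated test recovered 32.4% to 67.4% of genes changed by a factor of 2.

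DESeq2 called 1091 genes in cluster 14, 33 in Paneth-like, 17 in tuft-like and 15 in T cell-like cells. Without a filter on low counts the counts were 1149 in goblet-like, 85 in Paneth-like, 45 in enteroendocrine-like, 87 in tuft-like and 57 in T cell-like cells. With predicted doublets kept they were 3008 in cluster 14, 13 in tuft-like and 11 in T cell-like cells. At most 10% mitochondrial UMIs gave 3 in Paneth-like and 5 in enteroendocrine-like cells, clusters learned on WT cells gave 4 in Paneth-like cells, free RNA genes left out gave 1 in enteroendocrine-like cells and thinning to the smallest total gave 17 in tuft-like cells. Cells with at least 10000 UMIs gave 3054 in enterocyte-like and 8 in Paneth-like cells. WT1 alone gave 569 in epithelial, 235 in enterocyte-like, 42 in enteroendocrine-like and 28 in T cell-like cells, with its spread assumed like that of the KO libraries, and the target gene was at −0.48 without its call. Cluster 7 alone gave 601 and cluster 3 alone 64 in enterocyte-like cells, and stem-like with transit-amplifying-like cells gave 2560.

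The count model of class sizes called 0 classes at 1000 genes (edgeR, 2 at an unadjusted p under 0.05), 1 over all kept cells and 1 with called genes left out of the clustering. Classes without overlap were 2 at 1000 genes and 2 at 10000 UMIs. Camera with an estimated correlation called 0 of 261 lists (23 at an unadjusted p under 0.05) and fry 34, of which 33 were among the 104. The cycling share differed by 1.40 without thinning, 0.050 with doublets kept and 5.93 at 10% mitochondrial UMIs, against −2.32.

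Smaller values reversed too. Over all kept cells the abundance of the stem-like cluster was 0.18 (−0.26 in the report's setting) and its share differed by 0.35 (−0.58). With a library left out these ran from −0.49 to 0.12 and from −1.21 to 0.26. T cell-like abundance was −0.15 with TMM over classes (0.19) and ran from −0.096 to 0.77 with a library left out, and its share from −0.12 to 0.66. With doublets kept, log2 changes were −0.028 for Emp1 in stem-like cells, −0.078 for Hmgcs1 in stem-like cells and −0.011 for Pfkp in the same cells (cluster 14). They were 0.68 for Anxa13, 0.39 for Cd74, 0.13 for Krtcap2, 0.058 for Pycard and 0.21 for Rps2 in tuft-like cells. With cluster 3 alone they were −0.060 for Krt7 in enterocyte-like cells, 0.11 for Acadm, −0.11 for Bax, −0.15 for Hmgcs1, −0.045 for Insig1, −0.16 for Pcna, 0.082 for mt-Nd3 and 0.13 for mt-Nd4l, and in cluster 7 alone −0.22 for Krt7 and −0.14 for Pcna.

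The samples share only replicate numbers, and the labels give no pairing. The correlation of deviations was 0.085 for KO1 with WT1, −0.19 for KO2 with WT2 and 0.16 for KO3 with WT3, and not every sample correlated best with its own number. With the replicate number as a block, the counts were 849 in epithelial, 1106 in goblet-like, 37 in Paneth-like, 52 in enteroendocrine-like, 68 in tuft-like and 36 in T cell-like cells, 1 class size was called, the target gene was at −0.56 without its call (adjusted p = 0.0555, from edgeR), and the interaction with this block in place of the sample block gave 64.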

Other observations

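The test of the segment genes was written before its values were seen, and the genes singled out in the paragraph on cell death and metabolism come from the rule for named genes.

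Genes of cell death and metabolism moved within lists that did not pass fry. Ripk3, the kinase of necroptosis, rose in cluster 14 (log2 0.86), transit-amplifying-like (1.05), enterocyte-like (1.33) and goblet-like cells (0.79, called in 4 of the 6 fits with a library left out), and Mlkl, its effector, rose over all epithelial cells (0.85, called in 2 of the 6 fits). Members of the gasdermin C family fell in the same list, with Gsdmc2 (−1.91) and Gsdmc4 (−2.22) in transit-amplifying-like cells, each called in 4 of the 6 fits. Of 15 genes of that list over all epithelial cells, 3 rose and 3 fell (3 and 3 when adjusted over the list alone), the median was 0.07 and the mean −0.12, which differ in sign (fry adjusted p = 0.40). Of 15 genes of glycolysis and hypoxia in transit-amplifying-like cells, 5 rose and 1 fell (6 and 1 when adjusted over the list alone; median log2 0.26; fry adjusted p = 0.11), and camera at its preset correlation called this list (adjusted p = 0.015; 0.52 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 7.71 ± 1.22 to 14.1 ± 1.27 CPM (SD, n = 3).

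Some enzymes that handle xenobiotics rose in cluster 14 and transit-amplifying-like cells, where their list did not pass. Of 10 measured genes in cluster 14, 5 rose and 1 fell (6 and 2 when adjusted over the list alone; median log2 0.67; fry adjusted p = 0.064). Nqo1, a quinone reductase, rose from 19.6 ± 1.38 to 39.2 ± 3.86 CPM, and Gstm3, a glutathione transferase, from 22.7 ± 4.37 to 48.1 ± 11.8 CPM (SD, n = 3). In transit-amplifying-like cells 5 of 11 rose and 2 fell (5 and 3 when adjusted over the list alone; median log2 0.49; fry adjusted p = 0.18), and Gsta4 rose from 31.7 ± 8.91 to 88.4 ± 10.4 CPM (SD, n = 3). Of 30 ribosomal protein genes in cluster 14, 11 fell and 19 did not pass (16 fell when adjusted over the list alone), with a median of −0.16 (fry adjusted p = 0.073).

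Slc10a2, the ileal bile acid transporter, rose in KO enterocyte-like cells from 10.7 to 29.0 CPM (log2 1.44, edgeR adjusted p = 0.0243), and Lct, lactase, was at log2 −1.59 (adjusted p = 0.0536). The distal genes Fgf15 (log2 −1.06, adjusted p = 0.245) and Fabp6 (−0.58, adjusted p = 0.582) and the proximal gene Cyp3a11 (−0.26, adjusted p = 0.812) did not pass, and the distal ones went the other way. Such genes differ along the small intestine, so KO tissue from a more distal part could give the changes of Slc10a2 and Lct but not lower values of Fgf15 and Fabp6. Over the segment genes not seen before, 5 distal genes had a mean log2 change of −0.16 and 6 proximal genes of 0.18, a difference of −0.34 (SE over genes 0.54, upper limit 0.75). Of these genes Slc40a1 passed, a proximal gene that fell (log2 −2.15, adjusted p = 0.0194), as distal tissue would give, while the largest proximal rises, Pdx1 (1.38) and Cybrd1 (1.27), stood at or below 0.248 CPM. The members went both ways and the interval is wide, so this explanation cannot be told apart from an effect of the genotype.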
